A study of Zea mays with 6 samples.

How the data were processed

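RNA was extracted from pooled kernels and sequenced as Illumina libraries, per the labels' protocols. The labels describe 6 libraries in 2 groups, wild type and dek42, in 3 replicates each, all at 15 days after pollination. Files of 5 libraries were used, and wild-type replicate 2 was not analysed here. The deposited values are FPKM (fragment counts scaled by transcript length and by the number of mapped fragments), per the file headers, with one file per library. TopHat2 2.1.0, Cufflinks 2.2.1 and genome build B73 RefGen_v4 are named in the submitters' processing notes, without roles or settings. Whether reads were counted by strand, and how reads shared by several loci were divided, is not given in the sources used here. Either choice could move values between overlapping loci (1992 of those tested overlap another) and between near-identical copies.

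The labels give the molecule as total RNA, while the series description speaks of mRNA, and how RNA was selected before library preparation is not given in the sources used here. Each file listed the same 45764 rows. Rows are named by a coordinate span alone, and 14 spans that occur as 2 rows each, all at 0 FPKM, were left out because they could not be joined, which left 45736 loci. Of these, 473 lie on unplaced contigs, and 14205 are at 0 in every library. An exact 0 can be a failed estimate: 12 loci in wild-type replicate 1, and 3, 2, 1 and 1 in wild-type replicate 3 and dek42 replicates 1, 2 and 3, are listed at 0 while all other libraries have 10 FPKM or more. The reference table at hand covers 49888 genes of another assembly (Zm-B73-REFERENCE-NAM-5.0), and shares no identifier with the files. Gene names were therefore not assigned. The 18 gene lists and the set of genes with U12-type introns fixed before the data were examined were not analysed here.

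The number of reads per library was not given, and FPKM carries no counting interval. Depth was compared through loci of 1 to 4 kilobases with FPKM under 0.5, from the ratios of their values between libraries. Between wild-type replicate 1 and each other library the peak nearest equality lay at a log2 value ratio from -0.06 to 0.00. Ratios of whole reads also peak near equality where depths differ by a whole multiple, so this does not settle the relative depth. Loci of 157 bases gave no common step: the most common step between their values was 53, 16, 35, 26 and 28 FPKM in wild-type replicates 1 and 3 and dek42 replicates 1, 2 and 3.

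The test was chosen before the data were examined, for FPKM: limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 1), with genotype as the only term. Loci with at least 1 FPKM in at least 2 libraries were tested, two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes from the model are on the log2(FPKM + 1) scale, which understates the change of loci with low values. Folds given in the text as "fold" are ratios of mean FPKM. Counts of called loci changed at least 2-fold instead use a log2 change from the model of at least 1 in size. FPKM is relative to all mapped fragments, so a change in a few very abundant loci moves all others. For this reason counts of changed loci and the calls within groups of loci are also given after median-ratio scaling, in which each library is divided by the median ratio of its values to the geometric mean over libraries.

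Loci were grouped by chromosome, by span and in windows of 1 megabase holding at least 5 tested loci, choices made after the data were seen, since rows carry positions only. Windows were tested for an excess of rising or falling loci with a one-sided hypergeometric test against all tested loci on chromosomes and organelles. Arrays are spans shared by at least 4 tested loci in a window so called, plus all loci with the 2 spans so found on chromosome 6 (157 and 1812 bases). Their FPKM was summed per library. Sums and shares were compared with an exact two-sided permutation test over the 10 splits of 5 libraries, which cannot give a p below 0.1. The rule for single loci, fixed before the data were examined for the case that loci carry no names, took the 2 largest rises and the 2 largest falls among loci with adjusted p under 0.05, at least 5 FPKM in the higher group and all dek42 libraries on one side of both wild-type libraries. All 8431 called loci met the last condition, as did 66.4% of the loci tested, against 20% by chance.

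The model was tested on simulated data with normal noise. Of 20327 simulated loci, 100 were changed by 1 and 100 by 2 on the log2 scale, all with a mean log2(FPKM + 1) above 2. Of these, 35% and 99% were recovered, with 16 false calls. The simulation had few changed loci and no shift common to all loci, so it does not show how the model behaves under the broad shift in these data. The window test found 1 planted block of 8 falling loci and called no window without it. The alternatives were other pseudocounts (0.1, 0.5), other filters (none, and 5 FPKM), quantile normalization, median-ratio scaling, rescaling without the 50 most abundant loci, limma without the trend or with robust variance, the replicate number as a block, and leaving out each library. Restricting the loci to those above 0 in all 5 libraries, to spans over 500 bases, or to those outside the chromosome 6 block and unplaced contigs was added after seeing the data.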

Results

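RNA sequencing was carried out on pooled whole kernels of maize (Zea mays) collected 15 days after pollination. A whole kernel at this age holds endosperm, embryo and maternal tissue together. Wild-type kernels were compared with kernels of the mutant dek42 (dek42-ref in the sample titles), one of the defective kernel mutants, in which kernel development is impaired. Dek42 is known to encode an RNA-binding protein of pre-mRNA splicing, and the comparison asks which transcripts differ in level when it is disrupted. The labels describe 3 libraries per genotype. Wild-type replicate 2 was not analysed here, so wild-type replicates 1 and 3 (n = 2) were set against dek42 replicates 1, 2 and 3 (n = 3). The files name each transcribed locus only by its chromosome, start and end in B73 RefGen_v4, so loci are identified below by position. Gene names were not used here, the Dek42 locus itself was not analysed, and exonic, intronic or UTR annotation was not used. Nothing in the labels says that replicates came from separate plants, so p-values measure the spread between these pools, which may be technical.

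A total of 20327 loci reached 1 FPKM in at least 2 libraries. Summed FPKM was 1303510 and 1121968 in wild-type replicates 1 and 3, and 1463160, 1474743 and 1247823 in dek42 replicates 1, 2 and 3. Read totals were not given and the depth of each library is unknown. Values below are means ± SD over the libraries of a genotype. The log2(FPKM + 1) values of the wild-type libraries correlated across loci with r = 0.95. Those of the dek42 libraries correlated with r of 0.96 to 0.97, and values from different genotypes with r of 0.90 to 0.93 (across loci, which are not independent replicates). The first principal component held 69.2% of the variance and separated the genotypes.

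More loci reached 1 FPKM in the dek42 kernels, and a smaller part of the signal came from the most abundant ones. In wild type, 17560 ± 200.1 loci (SD, n = 2) were at 1 FPKM or more, against 19926 ± 401.0 (SD, n = 3) in dek42. After the median-ratio scaling described below the difference was smaller, 18400 ± 35 against 19286 ± 182 loci. The 50 most abundant loci, ranked by their mean over all 5 libraries, held 53.6% ± 0.079 of summed FPKM in wild type and 36.6% ± 2.0 in dek42. In these measures each dek42 library lay on the same side of both wild-type libraries. The exact two-sided permutation p was 0.1, which is the smallest that 2 against 3 libraries allow.

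On the deposited FPKM scale, 7966 loci were higher and 465 lower in dek42 (limma, Benjamini-Hochberg adjusted p under 0.05), or 41.5% of the loci tested. By the model, 4021 of them changed at least 2-fold (log2 change of at least 1 in size on the log2(FPKM + 1) scale), 3784 higher and 237 lower. The median tested locus was itself 0.54 higher on the log2 scale. When the libraries were brought to a common median (median-ratio scaling), the median was 0.01 and the split became 1619 higher and 1654 lower. Of the loci called on this second scale, all 1619 higher loci and 464 of the 1654 lower loci were called in the same direction on the deposited scale. Between the scales no call changed sign. This overlap and the lack of sign changes were largely fixed in advance, since the scaling lowered dek42 values relative to wild type throughout. Because the counts depend on the scale, directions below give both scales. These counts rest in part on single libraries: without dek42 replicate 3, the deposited scale gave 4894 higher and 287 lower loci and the median-ratio scale 377 and 316. Without dek42 replicate 2 the figures were 5160 and 325, and 583 and 511. Without dek42 replicate 1 they were 6883 and 374, and 748 and 744. Leaving out a wild-type library leaves 1 in that group. The counts on the median-ratio scale changed least without wild-type replicate 3. Fewer libraries also give less power, so a lower count need not come from the library left out.

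**Figure D1:**
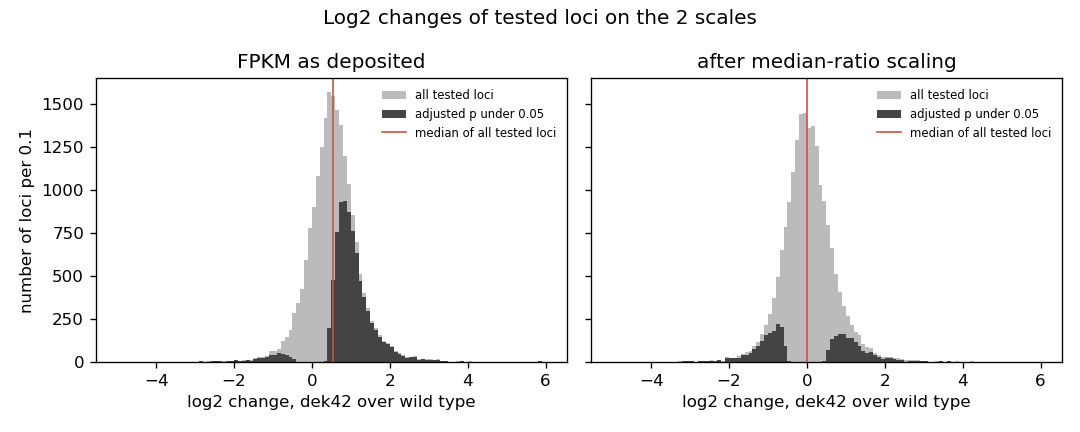
Histograms of the log2 change (dek42 over wild type, x axis) against the number of loci per bin of 0.1 (y axis), for FPKM as deposited (left, 20327 loci) and after median-ratio scaling (right, the 19909 loci tested on both scales). Grey is all loci, dark is loci with adjusted p under 0.05, values beyond the axis are drawn at its ends, and the median (line) sits at 0.54 on the left and close to 0 on the right.

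The most abundant wild-type transcripts included a group that fell steeply in dek42. Of 22 loci with a wild-type mean of 10000 FPKM or more, 15 fell and none rose on either scale (limma adjusted p of 0.0014 to 0.0069 as deposited), by 4.38-fold to 16.5-fold in mean FPKM. Of these 15 loci, 12 lie on chromosome 4 and 3 on chromosome 7. Together they held 28.0% ± 3.2 of summed FPKM in wild type (SD, n = 2) and 3.56% ± 0.45 in dek42 (SD, n = 3). The other 7 loci did not pass the test. Among them, the locus on chromosome 10 from 87401368 to 87401545, the most abundant of all, had 84154 ± 30149 FPKM in wild type and 82135 ± 12743 in dek42. The locus on chromosome 7 from 123982343 to 123983015 had 38088 ± 7225 and 24572 ± 788 FPKM (limma adjusted p = 0.41). The locus on contig B73V4_ctg153 from 12293 to 12450 had 29180 ± 15186 and 77291 ± 9608 FPKM (limma adjusted p = 0.16). Choosing loci by their wild-type mean favours falls over rises. Among the 133 loci with a mean over all libraries of 1000 FPKM or more, 61 rose and 24 fell as deposited. After median-ratio scaling 9 of them rose and 26 fell.

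On chromosome 4, 10 of the 12 loci lie between 5.8 and 6.4 megabases, most of them in groups of neighbouring loci with the same span, called arrays here. The arrays were chosen after the values were seen. All 5 loci of 706 bases from 6333302 to 6359146, with a median distance of 4451 bases between starts, fell on both scales. Their summed FPKM was 122129 ± 4324 in wild type and 14802 ± 3186 in dek42, 8.25-fold lower. Of 6 loci of 802 bases from 5835516 to 5940653, 5 fell on the deposited scale and 6 on the median-ratio scale. Their summed FPKM was 75806 ± 6624 in wild type and 14168 ± 1717 in dek42, 5.35-fold lower. For both arrays the exact two-sided permutation p was 0.1, the smallest possible. Members of an array share a span and may share reads, so the sums are firmer than the value of any one locus.

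Tested as windows of 1 megabase, the stretch of chromosome 4 from 5 to 6 megabases held 9 falling loci among 25 tested (one-sided hypergeometric test over 1580 windows, adjusted p = 3.6e-06), and that from 6 to 7 megabases held 6 among 23 (adjusted p = 0.0079). No other window held more falling loci than chance on the deposited scale. On the median-ratio scale the adjusted p values were 0.015 and 0.038. After quantile normalization both windows missed the threshold (adjusted p = 0.24 and 0.052). On the median-ratio scale the first window missed it without wild-type replicate 3 (adjusted p = 0.069). The second missed it without wild-type replicate 1 (adjusted p = 0.35), without wild-type replicate 3 (0.42) and without dek42 replicate 3 (0.36). Loci of one array are not independent, so these p-values are too small. Outside these windows, 2 of the abundant falling loci lie on chromosome 4 from 22579360 to 22580152 and from 31588159 to 31589091, which were 5.53-fold and 4.46-fold lower (limma adjusted p = 0.0033 and 0.0069).

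**Figure D2:**
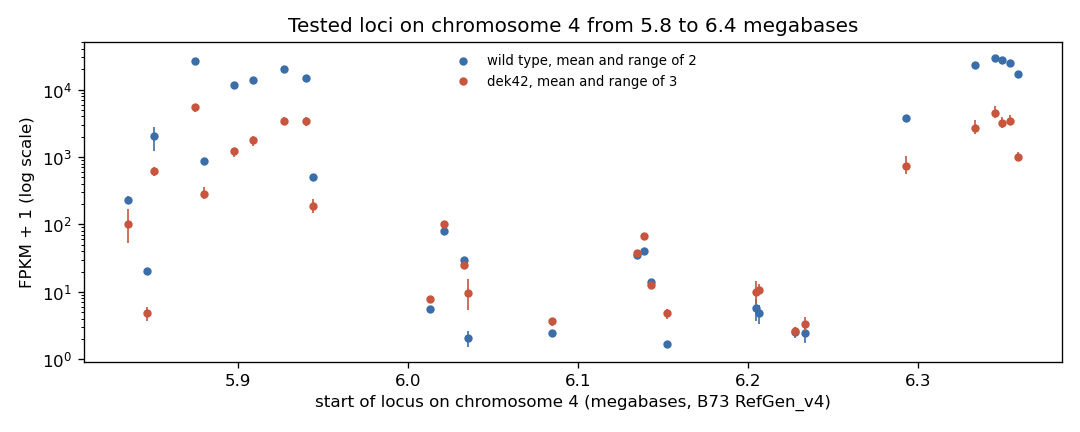
FPKM + 1 (log y axis) of the 29 tested loci on chromosome 4 between 5.8 and 6.4 megabases against the start of each locus (x axis, megabases). Points are group means and vertical lines the range of the 2 wild-type (blue) or 3 dek42 (red) libraries. The 2 clusters of abundant loci, at the left and right ends, lie lower in dek42. Of the less abundant loci between them none was called lower as deposited, and 2 were after median-ratio scaling.

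On chromosome 7, the locus from 19534999 to 19535722 went from 50263 ± 487 FPKM in wild type to 7158 ± 1269 in dek42, 7.02-fold lower (limma adjusted p = 0.0057). It overlaps a second falling locus, from 19535090 to 19549755, and how reads were divided between the pair is uncertain. The third falling locus on this chromosome, from 123954262 to 123955189, went from 15268 ± 1754 to 1258 ± 280 FPKM (12.1-fold, limma adjusted p = 0.0014). It lies within 30 kilobases of the abundant chromosome 7 locus that did not pass the test.

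An array on chromosome 10 went the other way. Of 19 tested loci of 305 bases between 3675250 and 3796744, spaced by a median of 1869 bases, 17 rose on the deposited scale and 12 on the median-ratio scale. None fell. Their summed FPKM was 161 ± 40 in wild type and 897 ± 219 in dek42, 5.58-fold higher (exact two-sided permutation p = 0.1). The window from 3 to 4 megabases held 13 rising loci among 31 tested on the median-ratio scale (hypergeometric adjusted p = 0.00045), the only rising window there. As deposited, where 39.2% of all tested loci rose, it did not stand out (adjusted p = 0.73), and after quantile normalization its adjusted p was 0.057. Of the 13 rising loci, 12 belong to the array and are not independent, so these window p-values are too small. On the median-ratio scale the window missed the threshold without dek42 replicate 1 (adjusted p = 0.068). Without dek42 replicate 2 or 3 its adjusted p was 1.

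A block of chromosome 6 from 12 to 15 megabases was higher in dek42. Of its 44 tested loci, 38 rose and none fell on the deposited scale, with a median log2 change of 1.94. On the median-ratio scale 9 rose and none fell, with a median of 1.33. The block held 2.90% ± 0.23 of summed FPKM in wild type and 11.3% ± 1.3 in dek42. The windows from 13 to 14 and from 14 to 15 megabases held more rising loci than chance on the deposited scale (17 of 20 and 14 of 15, hypergeometric adjusted p = 0.025 for each), and not on the median-ratio scale (adjusted p = 1 for each). Of the 20 loci in the first of these windows, 4 span 157 bases and 4 span 1812 bases. Loci that share a span are not independent, so these p-values may be too small. As deposited, no window held more rising loci than chance without wild-type replicate 1, without dek42 replicate 1 or without dek42 replicate 3.

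Loci of exactly 157 bases occurred in this block and elsewhere. Of the 37 tested, 8 lie on chromosome 6 and 27 on unplaced contigs. On the deposited scale 31 rose and none fell, and on the median-ratio scale 1 rose. Their summed FPKM was 74091 and 15143 in wild-type replicates 1 and 3, and 252510, 268348 and 118470 in dek42 replicates 1, 2 and 3 (exact two-sided permutation p = 0.2). The wild-type libraries differed widely at these loci. Loci of 1812 bases, 33 of them tested, had a summed FPKM of 773 and 2999 in wild-type replicates 1 and 3, and of 7883, 4028 and 4959 in dek42 (exact two-sided permutation p = 0.2). Of these, 28 rose as deposited and 2 after median-ratio scaling.

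**Figure D3:**
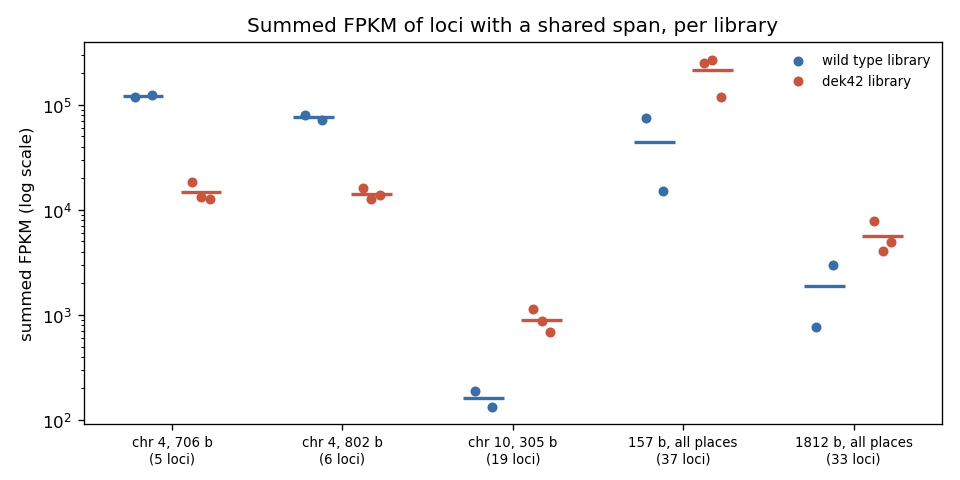
Summed FPKM (log y axis) in each library for 5 groups of loci that share a span (x axis, span in bases and number of tested loci). Points are libraries, blue for wild type and red for dek42, and horizontal lines are group means. The chromosome 4 arrays of 706 and 802 bases lie lower in dek42, the chromosome 10 array of 305 bases lies higher, and the 157-base and 1812-base loci lie higher but differ widely between the wild-type libraries.

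Short loci and organelle loci were counted as classes, and none of these classes stood apart from all other loci in the class test given below. Of all tested loci, 39.2% rose as deposited and 8.07% after median-ratio scaling. Of 71 tested loci of up to 200 bases, 44 rose and 1 fell as deposited, with a median log2 change of 2.94. After median-ratio scaling 13 rose and 1 fell. Such loci held 14.1% ± 2.9 of summed FPKM in wild type and 27.8% ± 5.4 in dek42 (exact two-sided permutation p = 0.2). Of 32 tested mitochondrial loci, 16 rose as deposited and 8 after median-ratio scaling, and none fell. Of 19 plastid loci, 5 rose as deposited and 2 after scaling, and none fell. Summed mitochondrial FPKM was 47.0 ± 10.7 in wild type and 262 ± 132 in dek42 (exact two-sided permutation p = 0.2), and 60.7 ± 12.4 and 216 ± 104 after median-ratio scaling (exact two-sided permutation p = 0.2). Tested against all other loci (limma camera, preset correlation 0.01), none of 20 classes of span or chromosome passed an adjusted p of 0.05. The lowest adjusted p was 0.25, for loci of up to 200 bases, and the same class had an adjusted p of 0.99 with an estimated correlation. For mitochondrial and plastid loci the adjusted p values were 0.74 and 0.98. The 10 numbered chromosomes had medians close together, from 0.52 to 0.55 as deposited.

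By the rule for single loci, the steepest rises were on chromosome 9 from 128658844 to 128659007 and on chromosome 1 from 66512569 to 66512766. The first is listed at 0 in both wild-type libraries and at 457, 1031 and 318 FPKM in dek42 replicates 1, 2 and 3 (limma adjusted p = 0.00063). The second is listed at 0 in both wild-type libraries and at 325, 527 and 119 FPKM in dek42 (limma adjusted p = 0.0014). Both span under 200 bases, where FPKM is least reliable, and no fold is given. The steepest falls were on chromosome 4 from 6358441 to 6359146 and on chromosome 1 from 177789386 to 177789677. The first, a member of the 706-base array, went from 16737 ± 111 to 1015 ± 156 FPKM, 16.5-fold lower (limma log2 change -4.05, SE 0.26, adjusted p = 0.0014). The second had 19.1 and 9.52 FPKM in wild type and is listed at 0 in every dek42 library (limma adjusted p = 0.0014). After median-ratio scaling the limma adjusted p values of these 4 loci were 0.0011, 0.0039, 0.0034 and 0.0039, in the same order.

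Among longer loci (over 500 bases and above 0 in every library, a selection made after the values were seen), the 3 largest rises in log2(FPKM + 1) were on chromosomes 2 and 10. The locus on chromosome 10 from 47326175 to 47327585 rose from 0.70 ± 0.65 to 152 ± 40 FPKM (limma log2 change 6.51, SE 0.30, adjusted p = 0.00048). The locus on chromosome 10 from 15330140 to 15332381 rose from 2.71 ± 1.39 to 210 ± 39 FPKM (log2 change 5.87, SE 0.26, limma adjusted p = 0.00048). The locus on chromosome 2 from 244318069 to 244318676 rose from 7.19 ± 0.52 to 472 ± 206 FPKM (log2 change 5.73, SE 0.40, limma adjusted p = 0.0014). By the same selection the 3 largest falls were the loci on chromosome 4 from 6358441 to 6359146 and on chromosome 7 from 123954262 to 123955189, given above, and the locus on chromosome 4 from 5897750 to 5898554. The last went from 11740 ± 302 to 1220 ± 197 FPKM, 9.62-fold lower (limma adjusted p = 0.0014). Each of these 6 loci also passed after median-ratio scaling.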

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

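The 4 single loci named by the rule and the 6 chosen among longer loci (9 in all, since 1 is in both) kept their direction and call under each alternative that gave a value. The array sums likewise kept their direction. These loci were chosen for large called changes, and the arrays from called windows, in the same libraries, so this was largely fixed in advance. The counts and the windows depended on the scaling. Against 8431 changed loci (7966 higher, 465 lower, 4021 at least 2-fold), quantile normalization gave 3112 (1521 higher, 1591 lower, 1564 at least 2-fold), median-ratio scaling 3273 (1619, 1654, 1700) and rescaling without the 50 most abundant loci 2527 (1175, 1352, 1700). These brought the median log2 change to -0.02, 0.01 and -0.0052, from 0.54. Other pseudocounts, filters and variance models kept the counts of higher and lower loci within 1.5 times. Leaving out one library gave 5181 to 7257 changed loci, 4894 to 6883 higher and 271 to 463 lower, each with fewer samples (a lone wild-type library is then assumed to vary like the dek42 libraries); the lowest counts were those without dek42 replicate 3 (5181 and 4894) and without wild-type replicate 1 (271 lower). On the median-ratio scale, the same gave 377 to 1608 higher and 316 to 1545 lower loci. A replicate block gave 4500 changed loci (4206 higher, 294 lower) and, on the median-ratio scale, 155 and 111; the labels give no shared origin to equal numbers, and same-numbered libraries correlated at 0.0057 and -0.015 in their deviations from the group means, so the number was not taken as a pairing. Windows with more falling loci numbered 2, against 3 with a pseudocount of 0.1, 0 after quantile normalization and 4 with the replicate block. Leaving out a dek42 library gave 2 to 4 (4 without dek42 replicate 2 or 3). Windows with more rising loci numbered 2, against 0 without a filter, with the filter at 5 FPKM, with robust variance, with spans over 500 bases and without the chromosome 6 block and contigs, 1 after quantile normalization, after median-ratio scaling, after rescaling without the 50 most abundant loci and with loci above 0 in all libraries, 3 with the replicate block, and 0 to 2 with one library left out. The cause of these window changes was not tested. The log2 change of summed FPKM moved from -3.04 to -3.67 (median-ratio) and -3.71 (without the 50 most abundant loci) for the 706-base array, from -2.42 to -3.04 and -3.07 for the 802-base array, and from 2.48 to 1.86 and 1.83 for the 305-base array. Leaving out one library gave 1.52 to 3.81 for all 157-base loci and 0.91 to 2.86 for all 1812-base loci (2.05 to 3.40 and 0.89 to 2.71 for those on chromosome 6 from 13 to 14 megabases); the extremes were those without wild-type replicate 1 or 3. The gene lists and the U12-intron set gave no value, and tests for count data were not run because the files hold FPKM.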

Other observations

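The loci in this paragraph were chosen after their values were seen. Some loci were listed at 0 throughout one genotype. In 29 loci every dek42 library had at least 5 FPKM and both wild-type libraries were at 0, and in 2 loci the reverse held. All 31 passed the limma test, which choosing loci by full separation of the genotypes largely fixed in advance. Some share a span and have identical values in every library, such as those on chromosome 1 starting at 287355135 and 287441734. The 31 loci are therefore not all independent. Of them, 29 (27 and 2) span at most 500 bases. The longer exceptions lie on chromosome 1, from 237572812 to 237573528 (76.4, 127 and 16.9 FPKM in dek42) and from 83058554 to 83059659 (9.48, 6.22 and 5.38 FPKM). Among the 133 loci with a mean of 1000 FPKM or more, the wild-type libraries differed at least 2-fold from each other in 52, of which 35 are 157-base loci and 9 span over 500 bases. Examples of these longer loci are those on chromosome 3 from 139335174 to 139335830 (18864 and 5722 FPKM in wild-type replicates 1 and 3, and 5134 to 6513 in dek42) and on chromosome 4 from 35888518 to 35889106 (12204 and 2243, and 2883 to 4149 in dek42). The highest and lowest dek42 libraries differed at least 2-fold in 40 of the 133.

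Of the tests below, those of the fragment share, the splits, the parts and the longer loci of the short and chromosome 6 pattern, the array sums and the chromosome segment were chosen only after the results were seen. The first pattern is that most loci were higher in dek42 on the deposited scale. Shallower sequencing of the wild type would affect mainly weak loci, yet the median log2 change was 0.54 for loci of 10 to 100 FPKM and 0.65 for loci of 100 FPKM or more, against 0.53 for loci of 1 to 10 FPKM. A candidate explanation is that abundant loci that fell left a larger share of fragments to the rest. From FPKM times span, the 14 non-overlapping loci with a wild-type mean of 10000 FPKM or more and an at least 2-fold lower mean in dek42, 1 of which did not pass the test, took 21.0% ± 0.89 of fragments in wild type and 3.42% ± 0.44 in dek42, which predicts a rise of 0.29 in all others, against 0.54 seen. This leaves out the overlapping pair of falling loci on chromosome 7: with the shorter of them the prediction is 0.35, and with both 1.39, where the longer would alone hold 40.9% of wild-type fragments. FPKM times span over all loci sums to 316% to 355% of fragments in a library, so spans overstate the share of some loci, and the effect of composition cannot be told apart from a real rise of many transcripts. Of the 10 splits of the 5 libraries into 2 and 3, only the real one (1 split) gave 8431 calls and the highest other gave 8, but 10 splits are too few for a share under 0.05.

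The second pattern is the rise of short loci and of the chromosome 6 block. Over these 107 loci the median absolute log2 ratio of the wild-type libraries was 5.92 times that of loci of like abundance (1.56 against 0.26), so RNA of these loci may enter libraries in variable amounts whatever the genotype. The parts differ, and leave this open: the ratio was 5.81 for the 44 loci of the block and 7.02 for the 31 loci of 157 bases outside it, while 17 of the 32 other short loci are listed at 0 in both wild-type libraries. The share of summed FPKM held by the block was 2.74% and 3.06% in wild-type replicates 1 and 3 and 12.03%, 12.08% and 9.83% in dek42 replicates 1, 2 and 3. The highest share was 1.12 times the lowest within wild type and 1.23 times within dek42. The lowest dek42 share was 3.21 times the highest wild-type share. In these few libraries the total thus varied less within a genotype than between genotypes. Its single loci were less steady, since 9 of the 44 block loci were higher in wild-type replicate 1 and 34 in replicate 3. The total therefore does not settle the variation of single loci, and a genotype effect stays open as untested. A bias of FPKM for short loci remains open for loci of up to 200 bases outside the block. Their median change lay 2.40 above that of all loci, which restates the pattern and cannot test the bias. The 28 longer loci of the block lay 1.30 above all loci too, which such a bias would not give.

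The third pattern is the fall of the chromosome 4 arrays. Reads moved between copies within an array would leave its sum as it was, but the smaller fall of a summed array was -2.42 on the log2 scale. Reads moved to or from loci of another span or place, which the sums leave out, were not tested. Median-ratio scaling (mean factor 0.773 in wild type and 1.20 in dek42) lowers every dek42 sum relative to wild type, so it could only deepen the fall. The smaller fall became -3.04, which does not test whether scaling of the libraries accounts for it. The highest dek42 library reached at most 0.225 of the lowest wild-type library. Libraries of the same genotype, each from pooled kernels, differed by at most 1.45-fold in the sum of either chromosome 4 array. The fall is larger than that spread, but the spread may be technical and need not measure differences between kernel pools. The arrays were also taken from windows called for falling loci, and the libraries are few (exact permutation p = 0.1 for both arrays). A difference between the pools therefore stays open. A difference between the stocks in the number or sequence of the copies, lower expression per cell, fewer of the cells that express these loci and slower kernel development in the mutant all remain open as hypotheses, and none was tested because each needs gene names, stages, tissues or the genomes of the stocks, which these files do not give.

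A segment of chromosome carried along with the dek42 allele could gather changed loci of both directions. Outside the arrays, 1 of 425 windows of 5 megabases held more changed loci than chance after median-ratio scaling, the first 5 megabases of chromosome 7 (12 rising and 9 falling among 56, hypergeometric adjusted p = 0.041). After quantile normalization the adjusted p was 0.28 and on the deposited scale 1.00, so the data do not settle it.

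Of the 37 loci of 157 bases, 59.5% have a locus of 1812 bases within 500 bases, at a median gap of 218 bases (interquartile range 2), and both may be parts of one repeated transcription unit. Against one unit read in a fixed proportion, the summed FPKM of 157-base over 1812-base loci was 95.9 and 5.05 in wild-type replicates 1 and 3, and 32.0, 66.6 and 23.9 in dek42 replicates 1, 2 and 3. Whether input or the quantification of short loci moved this ratio was not tested.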
